A study of Pseudomonas aeruginosa with 29 samples.

How the data were processed

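RNA was sequenced from cultures of Pseudomonas aeruginosa PAO1 before and during infection by 1 of 4 phages, in 29 libraries that the labels place in 13 groups. Per the labels, cells were stopped with a stop solution, RNA was extracted with an organic reagent and treated with DNase, ribosomal RNA was depleted, and libraries were made with a strand-specific kit. The aligner, the counting tool and the genome build are not given in the sources used here. DESeq2 is named in the submitters' processing notes.

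The main table, per the file headers, holds a count of reads per host feature and library, deposited without scaling. It lists 5668 features, of which 3 have an empty cell and were left out, so that 5665 were kept: 5568 coding genes, 63 tRNAs, 28 non-coding RNAs, 1 tmRNA and 5 pseudogenes. No phage genes are among them. The names, strands and positions printed here come from the authors' deposited table, for a single chromosome and an unnamed build, and no other coordinates were used. All but 1 of the coding genes, 5567, have a length that is a multiple of 3, so lengths are coding lengths. Of the kept features, 5623 carry a locus tag that is in the RefSeq gene table for this strain.

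The authors' deposited table of their own comparison gives, per the file headers, a mean signal per gene for sense and for antisense reads, log2 fold changes of infected against uninfected cells on both strands, and adjusted p-values. The authors' deposited patterns table marks which genes they called for each phage. A deposited library table gives read counts on the host outside ribosomal RNA, read counts on the phage and the percent of reads on the phage. It was used for the 4 libraries that its labels match to 1 library each, and 41 of its rows with values were not used. The percent of reads on the phage was set beside a 95% exact binomial (Clopper-Pearson) interval, which covers counting error only.

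Whether the counts keep the strand is not stated. The mean CPM of the libraries in the authors' core comparison had a Spearman correlation across 5556 coding genes of 0.968 with the authors' sense means and 0.996 with the sum of their sense and antisense means. In 89 genes whose antisense mean exceeds the sense mean by more than 2 times (and 50 counts), the ratio of the CPM to the sense mean had a median of 3.19, against 0.648 in 1921 genes with little antisense signal. Counts were therefore read as holding both strands, so that a gene and the transcripts on its other strand, or an overlapping gene, cannot be separated. The share of antisense reads in the authors' means is given where it is large.

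Group means were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on the deposited counts, TMM scaling, its filter by expression and Benjamini-Hochberg adjustment, with a threshold of 0.05. Library sizes were taken over coding genes. One fit with 5 groups, pooling the phases of each infection, gave the comparison of each phage with the 4 controls. Another, with the 13 groups, gave the comparisons of single phases. Groups of 1 library stayed in that fit but were not tested alone. The filter kept 5608 features, or 5603 without YuA early library 3. The standard error of a log2 fold change was taken as its size divided by the square root of the F value. Levels are CPM over coding genes after TMM scaling. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries in a group held identical values, and all pairs differed by more than the sampling noise. Equal replicate numbers were taken as pairs where all of 3 or more same-number pairs had a correlation of their deviations from the group means over 0.1. This held only for LUZ19 early and late libraries (0.184, 0.102 and 0.328), where 4 of the 6 libraries were closest to their own number, and the pairing comes from the numbers in the labels and this check alone. Groups that share only 2 numbers were outside this rule. Among them 14-1 middle and late had 0.382 for both pairs and YuA early and middle 0.253 and 0.37, while YuA middle and late had -0.44 and -0.549. The pooled comparisons counted all these libraries as independent. The check was applied after the calls with and without a replicate block over all libraries had been seen.

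The 32 gene lists, the tests, their samples and the naming rule were fixed before the data were examined. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01, and again with a correlation estimated from the data and with fry, which asks if a list moved on balance without comparing it with other genes. Adjustment ran over the 32 lists of a comparison. For each list the number of called members is given as adjusted over all genes tested and, where stated, adjusted over the list alone.

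Genes were named by rule. For each phage, called genes with a mean log2 CPM of at least 3 whose infected libraries all lay on the same side of all 4 controls were ranked by fold change, and the 10 highest and 10 lowest with a symbol and up to 3 each way without one could be named. The 5 highest and 5 lowest were taken for late against early, and up to 4 called members came from each list. A part of the rule for genes called in all 4 infections named none, because none was called. The genes recA, lexA, prtN, groEL, dnaK, rpoB, rpsL, rne, fliC and pilA could always be named. Any other gene is said to have been chosen after its values were seen.

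The steps were tested on simulated data drawn from the means and library sizes of the real genes, with 200 genes changed. Of 100 genes changed by 1 log2 unit, 27 were recovered for LUZ19, 26 for YuA, 10 for PEV2 and 25 for 14-1. Of 100 changed by 2 log2 units, 84, 86, 69 and 88 were recovered. None was called in the wrong direction. False calls numbered 6, 4, 1 and 6. A change of about 2 log2 units was thus mostly found and a change of 1 unit mostly missed, so a gene not called may still have changed. Late against early recovered 9 and 65 genes for LUZ19, 3 and 63 for YuA, and 8 and 58 for 14-1.

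Alternatives were size factors of DESeq2 1.42.0 within edgeR, the total count as the only scaling, no filter, the DESeq2 test, a replicate block, library sizes over all features, the mean of 3 phases, a fit of only the samples compared, a threshold of 0.01, a minimum fold, and leaving out each of the 29 libraries in turn. Others were added later and are named with their values. Because comparisons with the same 4 controls share chance values, 20 sets of unchanged groups were simulated against those controls, and the controls were also split. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The total count as the only scaling shifted the median of all genes by more than 0.1 log2 units in 6 of the 7 comparisons of phages or of late with early phases, by 0.292 for LUZ19, 0.359 for YuA, -0.189 for 14-1, 0.11 for LUZ19 late against early, -0.479 for YuA late against early and 0.131 for 14-1 late against early. Fold changes are relative to the TMM scaling.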

Results

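The data are transcript counts of Pseudomonas aeruginosa PAO1, a laboratory strain of an opportunistic pathogen, sampled before and during infection by the lytic phages LUZ19, YuA, PEV2 and 14-1. Cultures had been grown in lysogeny broth and infected with phage in large excess. There were 4 control libraries, taken just before phage was added (0 min). LUZ19 had 7 libraries, 3 early (5 min), 1 middle (10 min) and 3 late (15 min). YuA had 8, 3 early (5 min), 2 middle (15 min) and 3 late (25 min). PEV2 had 3, 1 each at 5, 10 and 15 min, and 14-1 had 7, 3 early (3 min), 2 middle (6 min) and 2 late (12 min). Controls from the later times were not analysed here, so in every comparison with the controls time in culture and infection changed together.

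Total counts per library ran from 199206 in LUZ19 late library 3 to 12653768 in LUZ19 early library 1, with a median of 5200903. Coding genes took 42.6% to 53.5% of the counts in the controls, 25.0% to 75.0% in the LUZ19 libraries and 33.3% to 72.5% in the PEV2 libraries. In 14-1 they took 47.6% to 95.5% in the early libraries and 81.2% to 88.0% in the middle and late libraries. YuA early library 3 stood apart. Only 5.51% of its counts fell on coding genes, and rnpB, the RNA of ribonuclease P, took 82.9%. Across coding genes its counts had a Spearman correlation of 0.249 with the authors' mean sense signal and of 0.846 with their mean antisense signal, against 0.89 to 0.955 and 0.453 to 0.554 in the other 28 libraries. Genes are not independent replicates, so these values only describe the libraries. The main counts of changed genes are also given without this library.

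**Figure D1:**
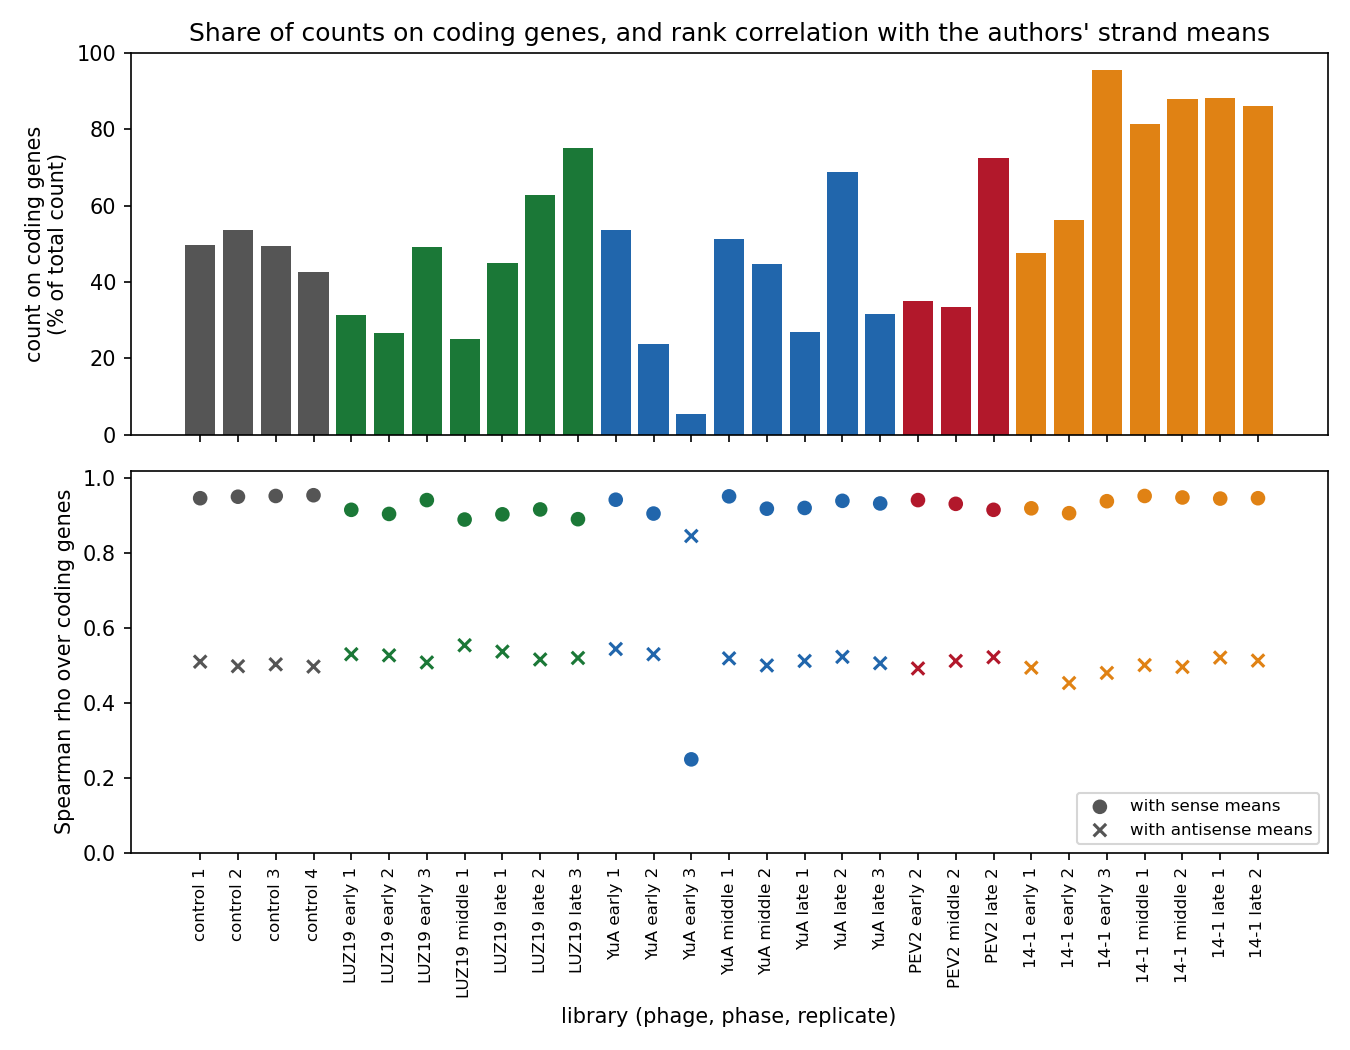
Each library's share of counts on coding genes (top, percent of the total count) and its Spearman correlation across coding genes with the sense (circles) and antisense (crosses) means of the authors' deposited table (bottom), coloured by phage. YuA early library 3 holds 5.51% and is the 1 library whose antisense value, 0.846, lies above its sense value, 0.249.

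The comparison of the 7 LUZ19 libraries with the controls asked which host transcripts changed during infection by this podovirus. Genes for the quinolone signal, a cell-to-cell signal of this species, rose. The anthranilate synthase genes phnA (PA1001, 1083972 to 1085564) and phnB (PA1002), which supply its precursor, rose by 2.11 ± 0.40 and 1.51 ± 0.33 on the log2 scale (SE, 7 against 4 libraries), with 32.8% antisense reads for phnB, which overlaps mvfR on the other strand. In the same locus pqsE (PA1000) rose by 2.07 ± 0.49, pqsC by 1.96 ± 0.46 and pqsD by 1.76 ± 0.46, with adjusted p from 0.00694 to 0.0347 over the 5 genes. The glycine cleavage genes gcvH2 (PA2446) and gcvT2 (PA2442) and the serine dehydratase gene sdaA (PA2443), which lie close together (2739762 to 2747073), rose by 2.48 ± 0.54, 2.41 ± 0.44 and 2.24 ± 0.44, with adjusted p of 0.0135, 0.0061 and 0.00743.

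Among the named genes that fell, the C4-dicarboxylate transporter dctA (PA1183, 1284513 to 1285823) fell by 5.03 ± 0.93 (adjusted p = 0.0061) and PA5530, a probable dicarboxylate transporter, by 4.05 ± 0.71 (adjusted p = 0.00493). For dctA the LUZ19 libraries held 9.57 to 65.3 CPM, control 4 held 76.2 and the other 3 controls 825 to 1480. For PA5530 the LUZ19 libraries held 15.1 to 55.5, control 4 held 59.9 and the other 3 controls 472 to 759. Both genes also varied within 14-1. Middle 1 and late 1 held 37 and 34.8 for dctA and 44.8 and 75.7 for PA5530. Middle 2 and late 2 held 1350 and 875 for dctA and 1180 and 723 for PA5530. The magnesium-responsive membrane protein gene oprH (PA1178) and the regulator gene phoP (PA1179) next to it fell by 2.35 ± 0.52 and 1.72 ± 0.36. Genes of the respiratory chain and ATP synthase were among the falls, with cyoA at -1.50 ± 0.28, nuoA at -1.62 ± 0.36 and atpB at -1.64 ± 0.44. The ribose transport gene rbsA rose by 1.58 ± 0.34. The pilus assembly gene pilC fell by 1.69 ± 0.35, the mechanosensitive channel gene mscL by 1.59 ± 0.45 and the ferritin gene bfrA by 1.43 ± 0.39. The copies PA5369.4 and PA4690.4 of an isoleucine tRNA both stood at 7.22 ± 1.73, and since near-identical copies share reads each value is uncertain. None of the 10 genes that could always be named passed, among them recA, the DNA damage recombinase, at 0.63 ± 0.46 (adjusted p = 0.453).

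Among the fixed lists, quorum sensing (15 genes) had 5 that rose, 0 that fell and a median of 0.79, and adjusted over the list alone 7 rose and 3 fell. Its call by camera was up, with adjusted p = 0.018, and 0.883 with an estimated correlation. The pyocin list (43 genes for phage-tail-like bacteriocins) had 3 that rose, PA0630 at 1.50 ± 0.30 (40.1% antisense reads), PA0626 at 1.31 ± 0.32 and PA0629 at 1.24 ± 0.31 (38% antisense reads), and a median of 0.466 (adjusted p = 0.0114, and 0.883 with an estimated correlation). Antisense reads make up 40.1% and 38.0% of the authors' means for PA0630 and PA0629. Denitrification and anaerobic arginine use (33 genes) had no called member but a median of 0.716 (adjusted p = 0.011, and 0.883 with an estimated correlation). Type IV pili (30 genes) had 1 that fell over all genes and 7 adjusted over the list alone, with a median of -0.501 (adjusted p = 3.35e-06, and 0.398 with an estimated correlation). O-antigen synthesis (20 genes; wbpB at -1.31 ± 0.36) had a median of -0.695 (adjusted p = 3.13e-05), NADH dehydrogenase I -0.706 and ATP synthase -0.684 (adjusted p = 0.00911 for both), nucleoid-associated proteins -0.96 (adjusted p = 0.0235) and ribosomal proteins -0.425 (adjusted p = 0.011). These calls were lost too, the adjusted p with an estimated correlation being 0.934 for ribosomal proteins and 0.883 for the other 4.

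In all, 78 genes rose and 73 fell of 5608 tested, and 364 and 338 without YuA early library 3, which kept all 151. The count was 15 without control 1 and moved by more than 1.5 times in 13 of the 29 fits that left out 1 library. With the total count as the only scaling 203 rose and 36 fell. By phase, 18 rose and 1 fell early and 97 rose and 48 fell late, and without YuA early library 3 the counts were 126 and 58 early and 315 and 332 late. Early calls numbered 1 without control 1.

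YuA, a siphovirus, was compared in the same way (8 against 4 libraries). Genes that add aminoarabinose to lipid A, a change of the outer membrane linked to resistance to cationic peptides, fell together. The neighbouring genes arnB (PA3552, 3979860 to 3981008), arnD, arnT, arnE and arnF (PA3558, ending at 3987293) fell by 1.52 ± 0.25, 1.63 ± 0.36, 1.48 ± 0.27, 2.42 ± 0.40 and 2.04 ± 0.33, with adjusted p from 0.00139 to 0.0165, and PA4773, in the operon for spermidine synthesis, fell by 2.20 ± 0.28 (adjusted p = 3.19e-05). These arn genes overlap by a few bases and share some reads. The regulator phoP fell by 1.53 ± 0.35 (adjusted p = 0.0225). The list of lipid A modification and spermidine genes had 9 of 12 members that fell, 0 that rose and a median of -1.40 (camera adjusted p = 6.74e-20). It was the 1 list of the 4 phage comparisons whose call held with an estimated correlation, at adjusted p = 0.0123.

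Among the genes that rose, the homogentisate dioxygenase gene hmgA (PA2009), of tyrosine breakdown, rose by 2.14 ± 0.38 and liuR (PA2016), regulator of leucine breakdown, by 1.70 ± 0.31 (adjusted p = 0.00257 for both), with 30.4% antisense reads for liuR. The pyoverdine synthetase genes pvdJ and pvdD rose by 1.16 ± 0.24 and 1.15 ± 0.23. PA1517 rose by 3.39 ± 0.59 (adjusted p = 0.00205), mexG by 1.48 ± 0.38, acnA, an aconitase, by 0.82 ± 0.21, PA0800 by 1.86 ± 0.43 and PA1892 by 2.24 ± 0.45, the last with 69.6% antisense reads. The PA1517 level split the YuA libraries across phases. Early 2, middle 2, late 1 and late 3 held 113 to 174 CPM. Early 1, early 3, middle 1 and late 2 held 16 to 29.8, against 5.21 to 10.8 in the controls. The cause of this split was not tested. Falls included the fatty acid desaturase gene desB and its repressor desT at -1.39 ± 0.33 and -1.23 ± 0.27, purA of purine synthesis at -1.28 ± 0.31, recO at -1.11 ± 0.23, roxR at -1.12 ± 0.28, fklB at -1.05 ± 0.25 and PA1053 at -2.22 ± 0.42. The tRNAs PA4541.2 (proline) and PA4277.2 (glycine) stood at -3.53 ± 0.73 and -2.37 ± 0.50. None of the always-named genes passed, with lexA, the repressor of the DNA damage response, at 0.82 ± 0.27 (adjusted p = 0.103).

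Pyoverdine and pyochelin genes, for iron-binding siderophores (36 genes), had 2 that rose, or 11 adjusted over the list alone, with a median of 0.636. Branched-chain amino acid degradation (12 genes) had 1 that rose, or 5 adjusted over the list alone, with a median of 1.01. Camera gave adjusted p = 1.87e-05 for both, and with an estimated correlation 0.0814 and 0.394. Pyocins had a median of 0.561 (adjusted p = 0.00035, and 0.765 with an estimated correlation). Lower lists were type VI secretion at -0.571 (adjusted p = 2e-05), type III secretion at -0.408 (0.000102), ATP synthase at -0.845 (6.75e-05), ribosomal proteins at -0.455 (1.12e-07), translation factors at -0.405 (0.00897), aminoacyl-tRNA synthetases at -0.281 (0.00309) and flagella at -0.178 (0.0244). With an estimated correlation the adjusted p was 0.68 for ATP synthase, 0.791 for aminoacyl-tRNA synthetases, 0.812 for flagella and 0.765 for the other 4. Without YuA early library 3, translation factors (adjusted p = 0.143), aminoacyl-tRNA synthetases (0.102) and flagella (0.392) lost their calls.

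In all, 25 genes rose and 36 fell, and 56 and 76 without YuA early library 3, which kept all 61. At least as many calls came from 5 of 100 random splits of the libraries, the real grouping included, and from 1 of 100 without YuA early library 3. With all libraries the count is thus not shown to exceed that of random grouping. The split with the most calls, 577, kept all 4 controls together in a group with part of the YuA libraries. Such a split still holds part of the contrast with the controls, so this test cannot show that the count is due to random grouping. The count was 13 without control 2, and with the total count as the only scaling 53 rose and 11 fell. Early in infection 468 genes rose and 116 fell, but without library 3 only 12 rose and 11 fell, and 21 genes were called both times. No gene was called by edgeR in the middle phase, where 375 had an unadjusted p under 0.05 and DESeq2 called 22, and without YuA early library 3 edgeR called 10 that rose and 6 that fell. Late in infection 16 rose and 24 fell, or 65 and 94 without that library, and 1 was called without YuA late library 3.

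PEV2, a podovirus, had 3 libraries of 1 phase each. All 3 carry replicate number 2 in their labels, so they may be successive times of 1 infection. In that case the SE and p-values below do not cover separate infections. Genes for DNA precursors rose: the ribonucleotide reductase genes nrdA (PA1156, 1251418 to 1254309) and nrdB (PA1155) by 6.36 ± 1.33 and 4.67 ± 1.04 (adjusted p = 0.021 and 0.0323), and the thymidylate synthase gene thyA (PA0342, 384733 to 385527) by 3.11 ± 0.55 (adjusted p = 0.00608). These rises rest on the late library, where nrdA held 103000 CPM, nrdB 24400 and thyA 4360, against 394 to 471, 313 to 353 and 163 to 215 in the controls, 1450, 666 and 290 in the early library and 729, 416 and 347 in the middle library. The iron-related genes PA4515, PA0472 and PA0471 rose by 2.88 ± 0.49, 2.56 ± 0.53 and 2.05 ± 0.42, and PA0717, of the filamentous prophage Pf4, by 3.00 ± 0.67. They rest on the late library too, with 437, 103, 87.7 and 44.2 CPM there against 21.1 to 29.2, 5.2 to 9.73, 8.71 to 10 and 0.491 to 4 in the controls, and without it they stood at 1.27, 1.25, 0.77 and 0.95, none called. The efflux genes PA3677 and PA3676 were the 2 that fell, by 2.08 ± 0.41 and 1.52 ± 0.32 (adjusted p = 0.0176 and 0.021), and neither was called without the late library. The chaperone gene dnaK, at 2.85 ± 0.93 (adjusted p = 0.283), the flagellin gene fliC, at 2.15 ± 0.77 (0.378), and the ribonuclease E gene rne, at 1.48 ± 0.50 (0.312), did not pass.

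Chaperones and heat-shock proteases (15 genes) had no member called over all genes but 5 that rose adjusted over the list alone, with a median of 1.22 (camera adjusted p = 3.69e-06, and 0.758 with an estimated correlation). The genes dnaK, dnaJ and hslU, the last 2 chosen after their values were seen, held 21500, 1910 and 2460 CPM in the late library. They held 4260, 541 and 833 in the early and 1550, 364 and 275 in the middle library. The list was not tested without the late library. Exopolysaccharides had a median of 0.469 (adjusted p = 5.1e-07), the TCA cycle 0.80 (0.00318), Pf4 with 1 of 15 genes risen 0.714 (0.00229), quorum sensing 0.601 (0.0461) and pyocins 0.417 (0.00641). In that order the adjusted p with an estimated correlation was 0.669, 0.984, 0.669, 0.984 and 0.988. Type III secretion, the needle apparatus (39 genes), had a median of -0.492 (1.3e-09, and 0.669 with an estimated correlation) and type IV pili -0.163 (0.00689, and 0.76). Nucleotide synthesis had 3 of 35 genes that rose, the 3 named above, and a median of 0.03 (adjusted p = 0.8). In all, 21 genes rose and 2 fell, or 41 and 12 without YuA early library 3, which kept all 23. Without the late library edgeR called 0, and without the middle library 59. With the total count as the only scaling 7 rose and 2 fell. No single PEV2 phase was tested, and 411 genes had an unadjusted p under 0.05.

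**Figure D2:**
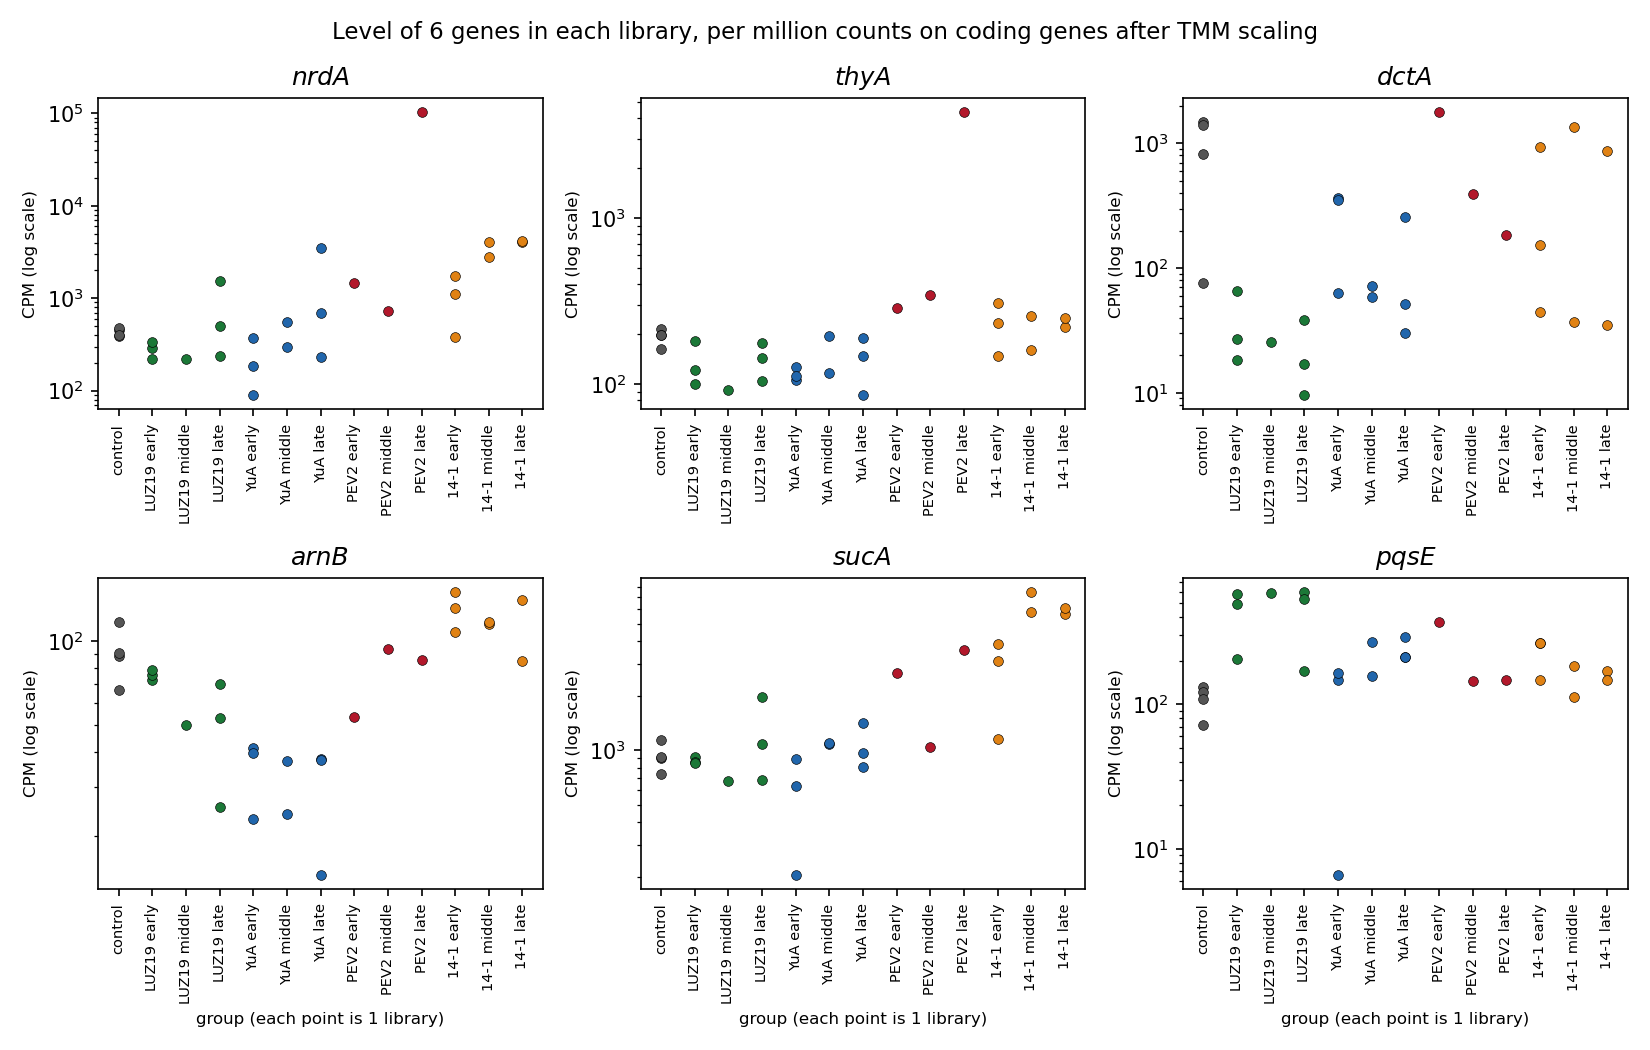
Level of 6 genes in each of the 29 libraries (CPM over coding genes after TMM scaling, log axis), with 1 point per library and groups along the x axis. The PEV2 late library lies at 103000 for nrdA and 4360 for thyA, and control 4 lies at 76.2 for dctA, below the other 3 controls.

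The myovirus 14-1 was compared with the controls in 7 against 4 libraries. Several genes of the TCA cycle rose. The 2-oxoglutarate dehydrogenase genes sucA, sucB and lpdG (PA1585 to PA1587, 1724244 to 1729852) rose by 2.36 ± 0.50, 2.61 ± 0.49 and 2.13 ± 0.46 and the isocitrate dehydrogenase gene idh (PA2624) by 1.90 ± 0.42, with adjusted p from 0.00302 to 0.00935. Over 42 alternative settings their lowest values were 1.21, 1.59, 1.41 and 1.04. Of these genes only sucA lost its call, in 1 setting. The TCA cycle list had 7 of 17 members that rose, or 13 adjusted over the list alone, and all 17 values were above 0, with a median of 1.39 (camera adjusted p = 9.92e-10, and 0.547 with an estimated correlation). Catabolic genes hmgA, faoA of fatty acid oxidation, gcdH, PA0506 and PA2265 rose by 2.20 ± 0.39, 2.17 ± 0.46, 1.63 ± 0.36, 3.11 ± 0.50 and 2.31 ± 0.41. Aminoacyl-tRNA synthetases had 5 of 22 that rose, or 12 adjusted over the list alone, with pheS at 1.59 ± 0.38, pheT at 1.55 ± 0.38, glnS at 1.52 ± 0.40 and lysS at 1.36 ± 0.41, and a median of 0.966 (adjusted p = 2.12e-08, and 0.594 with an estimated correlation). Over 42 alternative settings the lowest values of these 4 genes were 1.035, 0.48, 0.67 and 0.62. They lost their calls in 3, 7, 8 and 27 of the settings.

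The SOS response and DNA repair list, for DNA damage, had 4 of 18 that rose (4 rose and 1 fell adjusted over the list alone), lexA by 1.57 ± 0.28, PA3413 by 1.90 ± 0.43, recN by 1.22 ± 0.34 and uvrB by 0.72 ± 0.20, with a median of 0.562 (adjusted p = 0.00289, and 0.547 with an estimated correlation). The pyocin activator gene prtN rose by 1.83 ± 0.49, while the pyocin list had 1 of 43 called and a median of 0.213 (adjusted p = 0.495). In only the libraries with a coding share under 60% and without YuA early library 3, a setting chosen after the data were seen that keeps 14-1 early libraries 1 and 2, recN stood at 0.19 (adjusted p = 0.676), prtN at 0.32 (0.618) and uvrB at 0.48 (0.174), while lexA and PA3413 still passed. Without any 1 of the 4 controls recN, prtN and uvrB were not called. recA stood at 0.85 ± 0.46 (adjusted p = 0.27), dnaK at 1.32 ± 0.78, groEL at 1.04 ± 0.72, rpoB at 1.02 ± 0.53, rpsL at 0.95 ± 0.65 and fliC at 1.47 ± 0.67, none of which passed. Without YuA early library 3 rpoB passed, at adjusted p = 0.00965. The ribonuclease gene rne rose by 1.53 ± 0.44. Lipid A modification and spermidine genes had 5 of 12 that rose, with pmrA, PA4774 and arnA, chosen after their values were seen, at 1.38 ± 0.27, 1.58 ± 0.33 and 1.28 ± 0.30, and a median of 0.576 (adjusted p = 3.4e-05, and 0.547 with an estimated correlation). NADH dehydrogenase I had 2 of 13 that rose, nuoE and nuoD by 1.24 ± 0.34 and 1.14 ± 0.33, with a median of 0.997 (adjusted p = 0.00289, and 0.83 with an estimated correlation). Its first gene nuoA stood at -1.06 ± 0.36 (adjusted p = 0.0741, and 0.0301 without YuA early library 3).

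Other rises were the ribosomal gene rpmC at 2.12 ± 0.52, pqsC at 1.81 ± 0.45, the efflux gene mexC at 2.55 ± 0.60 (0.43, adjusted p = 0.752, in the libraries under 60%), the pyoverdine receptor gene fpvA at 1.52 ± 0.43, cyoA at 1.02 ± 0.28, gyrA at 1.10 ± 0.32, pyrC at 1.31 ± 0.36, ahpF at 0.97 ± 0.26 and the flagellar genes flgL and flgE at 1.02 ± 0.29 and 0.98 ± 0.27. Over 42 alternative settings gyrA, pyrC, ahpF, flgL and flgE had lowest values of 0.83, 0.45, 0.52, 0.47 and 0.68. They lost their calls in 18, 12, 10, 14 and 12 of the settings. Falls were atpI at -1.96 ± 0.56, ipk at -2.84 ± 0.68, the sigma factor gene fpvI at -1.21 ± 0.33, desT at -1.35 ± 0.28, tadB at -1.43 ± 0.33, crfX at -1.37 ± 0.37, phzC2 at -1.49 ± 0.41 (which has a near-identical copy), pslK at -1.21 ± 0.30, pilS at -1.09 ± 0.28, and snr1 and opdK at -1.39 ± 0.32 and -1.35 ± 0.30, with 75.3% and 41.5% antisense reads. The tRNAs PA0905.2 (arginine) and PA0668.3 (alanine) stood at -3.45 ± 0.69 and -3.44 ± 0.75. Small RNAs (9 genes) had none called and a median of -1.49 (adjusted p = 8.81e-05, and 0.594 with an estimated correlation). Branched-chain amino acid degradation (median 0.85, adjusted p = 0.00506), nucleotide synthesis (0.434, 0.00464), DNA replication (0.424, 0.0138), ribosomal proteins (0.554, 0.0138) and quorum sensing (0.581, 0.0333) were the other lists called, all up.

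These 5 calls were lost as well, the adjusted p with an estimated correlation being 0.784 for branched-chain amino acid degradation, 0.83 for nucleotide synthesis and quorum sensing, 0.837 for DNA replication and 0.975 for ribosomal proteins. In all 148 genes rose and 127 fell, or 448 and 389 without YuA early library 3, which kept all 275. The count was 70 without control 2, and with the total count as the only scaling 63 rose and 175 fell. The middle and late 14-1 libraries also had coding shares of 81.2% to 88.0%, above the controls, and early library 3 had 95.5%. Of 48 named genes called in 14-1, 22 were smaller by more than 1.5 times in the libraries under 60% and 29 were not called there, and with the coding share as a covariate, also chosen after, 21 and 26. By phase 76 rose and 44 fell early, 118 and 72 in the middle and 173 and 133 late, and without YuA early library 3 the counts were 360 and 323, 441 and 386, and 423 and 468. Early calls fell to 0 without control 1 (edgeR; 1042 genes had an unadjusted p under 0.05 with all libraries, and DESeq2 called 323).

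**Figure D3:**
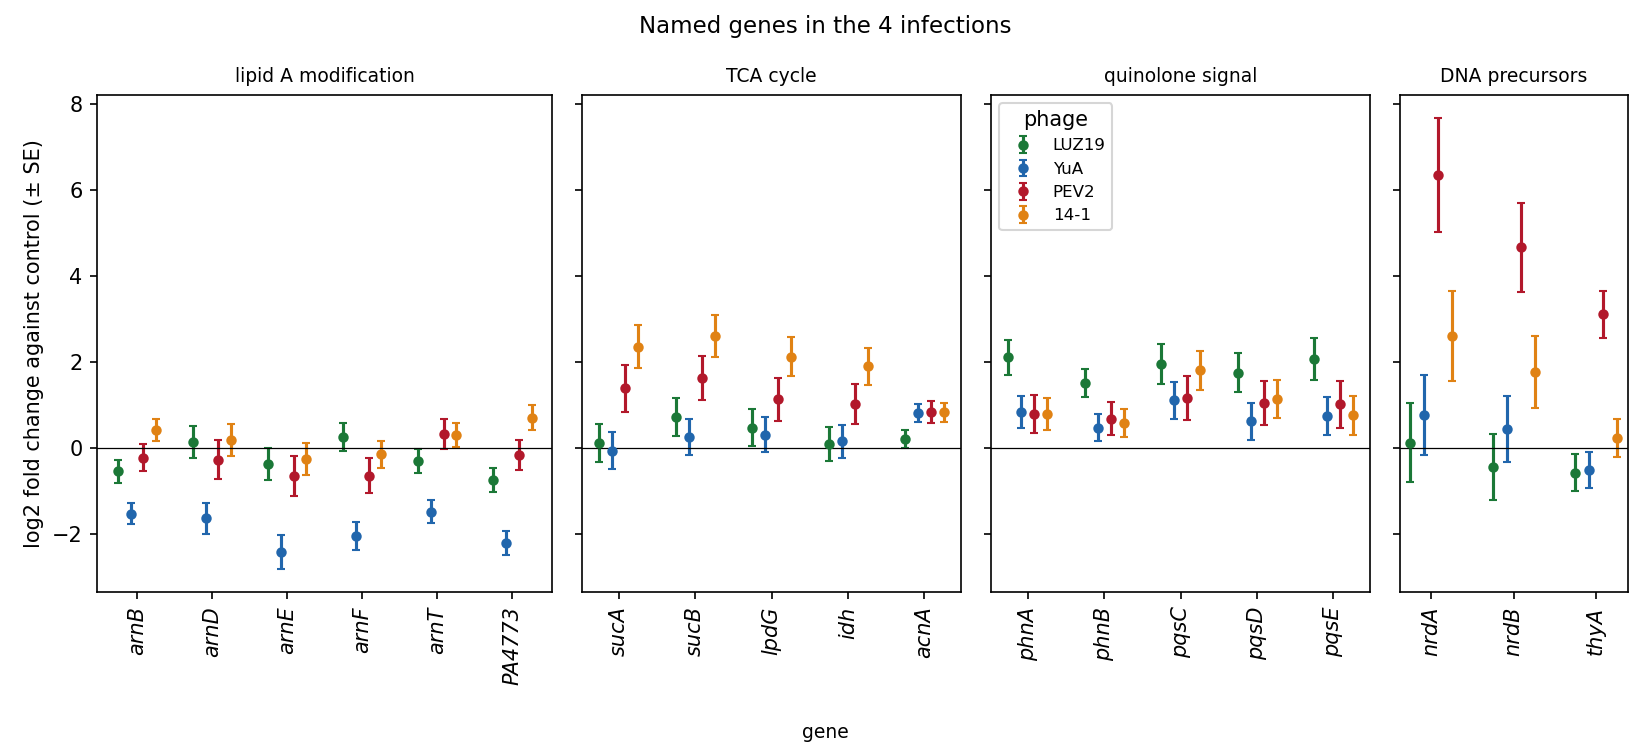
Log2 fold change against the 4 controls for genes of lipid A modification, the TCA cycle, the quinolone signal and DNA precursors, with bars of 1 SE, coloured by phage and shown whether or not a gene was called. The lipid A genes lie lowest in YuA (arnE at -2.42), the TCA genes sucA and sucB highest in 14-1 (2.36 and 2.61), the quinolone genes highest in LUZ19 (phnA at 2.11) and nrdA highest in PEV2 (6.36).

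Late against early libraries of the same infection asked how the response moved with time. The controls do not enter this contrast, but like all other libraries they enter the fit's estimate of the spread. In 14-1 (2 against 3 libraries) the genes for the siderophore pyochelin rose late, with pchC (PA4229) up by 3.50 ± 0.63, pchD (PA4228) by 2.94 ± 0.52 and pchF (PA4225) by 2.80 ± 0.46, and adjusted p of 0.00509, 0.00478 and 0.00311. The O-antigen genes wzy (PA3154, 3537808 to 3539124), wzx, wbpG and wbpH fell by 3.68 ± 0.67, 3.43 ± 0.68, 3.40 ± 0.94 and 3.08 ± 0.78. The oxidative stress regulator gene ospR rose by 2.93 ± 0.41 (adjusted p = 0.000608) and mexC by 2.80 ± 0.65, and rsaL, a repressor in quorum sensing, fell by 3.59 ± 0.76. Among genes chosen after their values were seen, ptrB rose by 2.33 ± 0.52, dnaJ by 2.49 ± 0.57, hslU by 2.37 ± 0.64, PA3414 by 2.32 ± 0.52 and recN by 1.50 ± 0.36, and the signal genes rhlI and rhlR fell by 2.17 ± 0.49 and 1.41 ± 0.36, fimU by 1.69 ± 0.43 and pilZ by 2.58 ± 0.69. The pyocin activator gene prtN rose by 2.56 ± 0.45, and the pilin gene pilA stood at -3.40 ± 1.36 (adjusted p = 0.182, and 0.0305 without YuA early library 3).

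**Figure D4:**
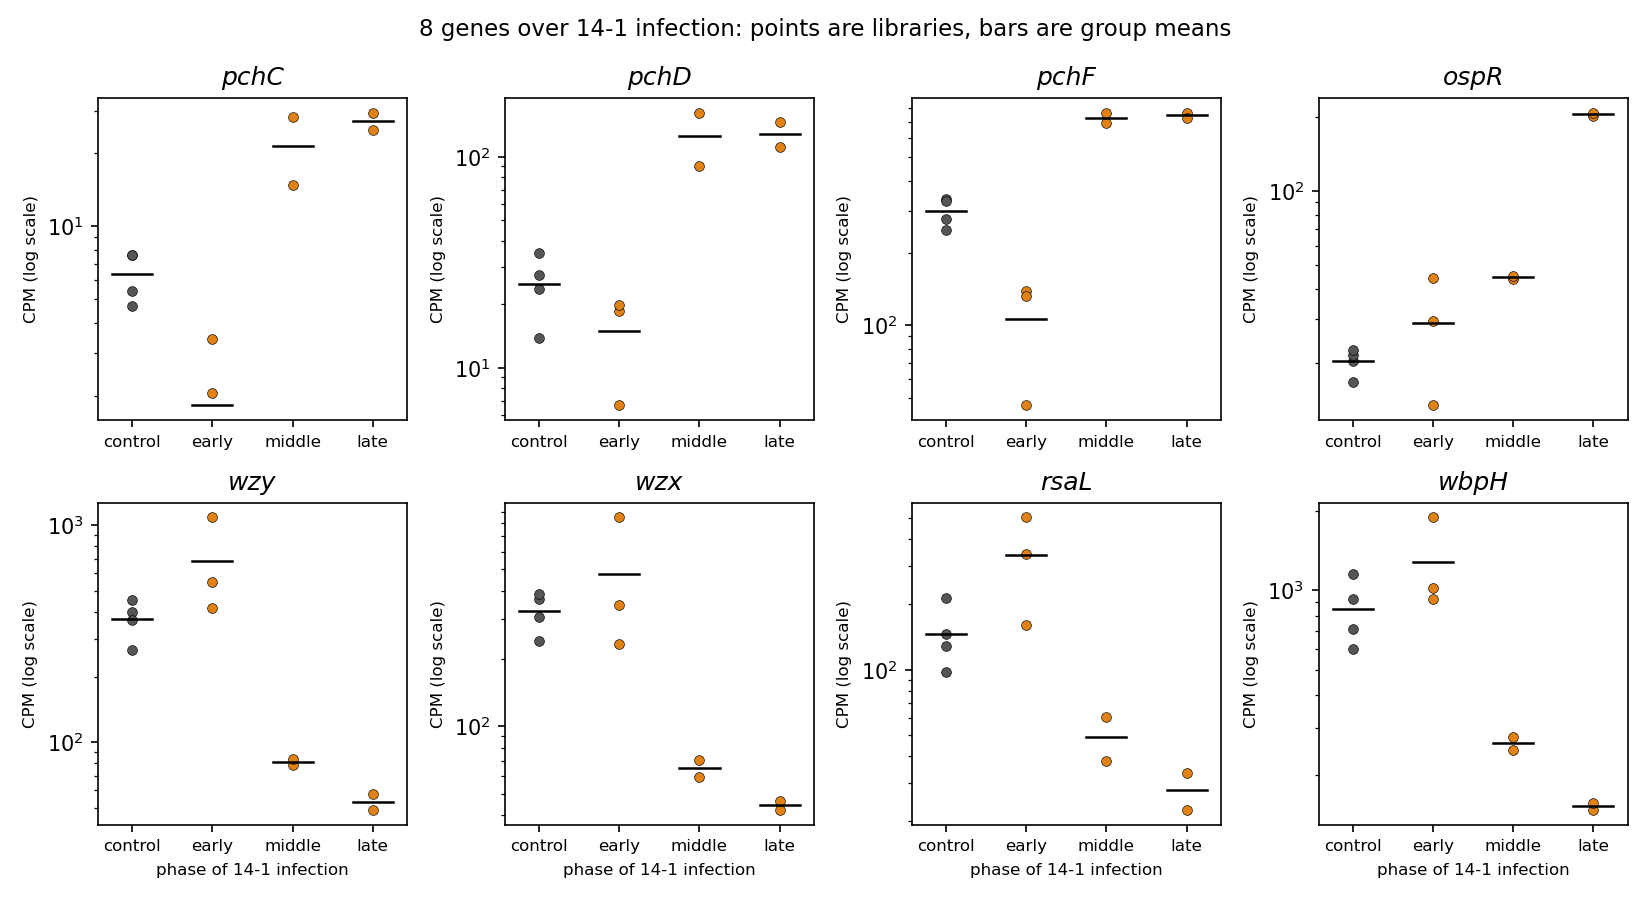
Level of 8 genes in the controls and the 3 phases of 14-1 infection (CPM after TMM scaling, log axis; points are libraries, bars are group means, and a library without counts is not drawn). The late libraries hold 24.9 and 29.4 for pchC against 0 to 3.43 early, and 48.8 and 57.7 for wzy against 415 to 1090 early.

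In 14-1 late against early, O-antigen synthesis had 7 of 20 genes that fell, or 13 adjusted over the list alone, with a median of -1.45 (camera adjusted p = 8.72e-13, and 0.187 with an estimated correlation). Pyoverdine and pyochelin had 12 of 36 that rose, all in the pyochelin cluster (PA4218 to PA4231), while adjusted over the list alone 14 rose and 9 fell. Its median was -0.159, its mean 0.373 and its call up (adjusted p = 0.0158, and 0.499 with an estimated correlation). Quorum sensing fell with a median of -0.775 (0.000476; 0.241 with an estimated correlation), the Pf4 prophage with -1.11 (0.000222; 0.187), type IV pili with -0.429 (0.00193; 0.423), small RNAs with -2.49 (0.00874; 0.556), nucleoid-associated proteins with -0.955 (0.0189; 0.556), ribosomal proteins with -0.339 (0.0206; 0.795) and flagella with -0.273 (0.0189; 0.764). Chaperones were up with a median of 1.11 (0.0054; 0.617 with an estimated correlation), type VI secretion with 0.769 (0.000788; 0.556), denitrification with 0.854 (0.000801; 0.499), exopolysaccharides with 0.547 (0.00668; 0.499), branched-chain amino acid degradation with 0.837 (0.00779; 0.556), phenazine synthesis with 0.68 (0.0158; 0.494) and multidrug efflux with 0.60 (0.0206; 0.423). In all 75 genes rose and 76 fell, or 231 and 372 without YuA early library 3, and 8 were called without 14-1 late library 1. Of 20 named calls, 19 were lost in a fit of only the libraries compared.

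In LUZ19 (3 against 3) edgeR called no gene between late and early libraries, where 357 had an unadjusted p under 0.05 and DESeq2 called 12, and 2 rose without YuA early library 3. With a replicate block over these 6 paired libraries, added after the results were seen, 6 rose and 2 fell without YuA early library 3. The same replicate block also put type VI secretion HSI-I down, with a median of -0.279 (camera adjusted p = 0.0309, and 0.995 with an estimated correlation), against 0.0557 without it. The pyocin list had 13 of 43 that rose adjusted over the list alone and a median of 0.753 (camera adjusted p = 8.85e-17, and 0.121 with an estimated correlation). The SOS response list had a median of 0.42 (adjusted p = 0.000814, and 0.121 with an estimated correlation). Chaperones (0.625), the TCA cycle (0.503), nucleotide synthesis (0.322), aminoacyl-tRNA synthetases (0.287) and quorum sensing (0.33) were also up, and O-antigen synthesis (-0.469), lipid A modification (-0.429) and small RNAs (-1.27) down, with camera adjusted p from 0.00147 to 0.0459 and adjusted p = 0.996 with an estimated correlation for all 8.

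In YuA (3 against 3) edgeR likewise called no gene between late and early libraries, where 1049 had an unadjusted p under 0.05 and DESeq2 called 409, and again none without early library 3. The early and the late group each held libraries of high and of low PA1517, so neither group was uniform. Of the 32 lists 20 were called by camera, 16 of them up. Ribosomal proteins (53 genes, all 53 values above 0) had a median of 1.42 (adjusted p = 1.88e-20, and 0.261 with an estimated correlation), translation factors 1.26, ATP synthase 1.04, NADH dehydrogenase I 0.955, the TCA cycle 0.935, RNA polymerase 0.822, chaperones 0.819, aminoacyl-tRNA synthetases 0.786, nucleotide synthesis 0.739, DNA replication 0.64, RNA turnover 0.604, nucleoid-associated proteins 0.547, O-antigen synthesis 0.534, flagella 0.444, pyocins 0.392 and the arginine succinyltransferase pathway 0.995. Denitrification (-1.16), phenazine synthesis (-0.632), exopolysaccharides (-0.623) and lipid A modification (-0.545) were down. All 20 calls were lost with an estimated correlation, the lowest adjusted p being 0.261. Without early library 3, camera again called 20 lists, 16 of them up, and the medians were smaller, 0.87 for ribosomal proteins (adjusted p = 2.36e-15, and 0.192 with an estimated correlation) and 0.753 for translation factors. Translation factors then held with an estimated correlation (adjusted p = 0.0379), and fry, which had called 15 lists, called 2. With the total count as the only scaling 13 genes rose and 817 fell. Oxidative stress and envelope stress were the 2 lists that camera called in none of the 7 comparisons with all libraries, while fry called oxidative stress here (adjusted p = 0.0397).

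The title of the series asks for a response conserved between phages. No gene was called in the same direction in all 4 infections (independent lists would share 3.44e-05 that rose and 3.78e-06 that fell), nor in 3, while 11 rose and 19 fell in a pair of infections. Without YuA early library 3 these counts were 43 and 66 in 2 infections, 4 and 16 in 3, and 1 in all 4, the cytochrome gene cc4 (PA5490), chosen after its values were seen, at -0.80 in LUZ19, -1.14 in YuA, -1.29 in PEV2 and -0.91 in 14-1. In 20 simulations of unchanged groups against the same controls no gene was shared by 4, nor was one after the controls were split, with all libraries or without YuA early library 3. The simulations called a mean of 0 genes with all libraries and 0.1 without that library. Sharing could therefore hardly arise in them, and they do not measure chance overlap at the real numbers of calls. Without that library independent lists would share 0.00213 genes that rose and 0.000682 that fell. A total of 6 genes rose in 1 infection and fell in another (35 without YuA early library 3). With all libraries PEV2 called only 21 genes that rose and 2 that fell, so few genes could be shared by 4. Changes of 1 log2 unit were also mostly missed, so the lack of shared calls does not argue against a conserved response. Of 5608 genes, 930 had values above 0 in all 4 infections and 603 below 0, but the shared controls also produce such agreement.

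Fold changes of the infections were related to different degrees across genes. The Pearson correlation was 0.441 for YuA and PEV2 (0.323 simulated from the shared controls, 0.268 with the controls split), 0.413 for LUZ19 and YuA (0.427 and 0.278), 0.404 for PEV2 and 14-1 (0.311 and 0.243), 0.313 for LUZ19 and PEV2 (0.307 and 0.162), 0.232 for YuA and 14-1 (0.446 and 0.115) and 0.056 for LUZ19 and 14-1 (0.43 and -0.037). The covariances in the same order were 0.168, 0.186, 0.157, 0.123, 0.104 and 0.026, against simulated values of 0.045, 0.044, 0.045, 0.045, 0.045 and 0.045, which leaves differences of 0.123, 0.143, 0.113, 0.078, 0.059 and -0.019. YuA and 14-1 shared 5 genes that rose and 10 that fell (0.66 and 0.815 for independent lists), LUZ19 and YuA 4 and 4 (0.348 and 0.469), LUZ19 and 14-1 2 and 3 (2.06 and 1.65) and YuA and PEV2 0 and 2 (0.0936 and 0.0128). Without YuA early library 3 these were 13 and 33 (4.48 and 5.28), 11 and 27 (3.64 and 4.58), 23 and 42 (29.1 and 23.5, with 29 in opposite directions) and 1 and 8 (0.41 and 0.163). The simulations gave 0 for these pairs, but they called almost no genes, so this does not measure chance overlap. The infections also differed: 2593 genes varied between the 4 phages in a single test without the controls (3175 without YuA early library 3).

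The authors' own comparison pooled late libraries of the 4 phages, PEV2 middle and the controls, and the authors' deposited table called 95 genes higher and 237 lower, at an adjusted p under 0.05 and a log2 fold change of at least 1. Those calls are on sense reads, whereas the counts used here were read as holding both strands, so the measures differ. The same 10 infected libraries against the 4 controls, a comparison chosen after the files were seen, gave 8 genes that rose and 47 that fell of 5563 tested with edgeR, without a minimum fold, where 819 had an unadjusted p under 0.05 and DESeq2 called 213. Of these 55, 47 were also called in the authors' deposited table, and 324 of its 332 had the same sign here, with a Pearson correlation across 5560 genes of 0.758. The patterns sheet of the authors' deposited table marked 430 genes for LUZ19, 475 for YuA, 601 for PEV2 and 651 for 14-1, with 50 marked for all 4. Of the genes called here it marked 83 of 151, 32 of 61, 21 of 23 and 169 of 275, and of those called without YuA early library 3 the authors' deposited table marked 209 of 702, 53 of 132, 39 of 53 and 320 of 837.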

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

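Values were compared within groups by a rule fixed before the data were seen, which marks a library lying far from all others of its set. It was applied to 250 groups of values and marked 26; chance alone marks about 1 group in 20. In CPM and beside the range of the other libraries, LUZ19 early 3 was apart for gcvH2 (18.6; 47.7 to 77.4), sdaA (15.9; 51 to 76.2) and nuoA (356; 92.5 to 165). YuA early 3 was apart for phoP (26.5; 88 to 229), PA1892 (56.2; 7.23 to 15.8), purA (109; 377 to 686), recO (13.2; 24.6 to 34.2), fklB (52.9; 143 to 215) and PA4541.2 (6.62; 104 to 207), and for its rank correlation with the authors' sense means (0.249; 0.906 to 0.952). YuA late 2 was apart for PA0800 (31.5; 5.87 to 12.3).

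In 14-1 early 1 the genes glnS (343; 693 to 975), lysS (434; 846 to 1260), nuoD (359; 730 to 1130), ahpF (140; 215 to 261), arnA (135; 269 to 374) and fliC (1250; 2550 to 4250) were low and PA0905.2 was high (396; 23.3 to 73.1). In 14-1 early 2 desT (17.7; 32.9 to 50.2) and gyrA (1740; 2270 to 2760) were low. Both libraries came from 3 min, but the ranges beside them include the other 14-1 libraries of that time. In early 2 and early 3 glnS held 693 and 948, lysS 846 and 1260 and arnA 319 and 294. Time alone therefore does not set early 1 apart for these genes. Among the controls, control 3 had a low total count (3237139; 5267766 to 5779023), control 1 was low for PA0630 (16.4; 23.5 to 24.6) and fklB (279; 362 to 369), control 2 was high for PA1053 (3290; 1850 to 1900), and control 4 was high for PA0905.2 (1580; 791 to 885) and low for pilS (135; 167 to 172).

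Direct tests between infections, without the controls, were listed because the phages differed. They called 984 genes for LUZ19 against YuA, 305 for LUZ19 against PEV2, 2200 for LUZ19 against 14-1, 47 for YuA against PEV2, 1772 for YuA against 14-1 and 167 for PEV2 against 14-1. Without YuA early library 3 these counts were 1400, 729, 2792, 107, 1845 and 479. The change from early to late differed between YuA and 14-1 for 131 genes, or 311 without that library. Between LUZ19 and 14-1 edgeR called 0, where 519 had an unadjusted p under 0.05 and DESeq2 called 62, and 65 without it. Between LUZ19 and YuA edgeR called 0 with or without it, where 615 had an unadjusted p under 0.05 and DESeq2 called 12 with all libraries. Deposited values that no comparison used were also listed: the percent of reads on the phage, 23.26 in LUZ19 middle (95% exact binomial interval 23.23 to 23.28), 41.19 in PEV2 early (41.16 to 41.23), 48.42 in PEV2 middle (48.38 to 48.46) and 70.99 in PEV2 late (70.96 to 71.02), and 281 genes with an antisense call in the authors' deposited table. For PEV2 middle the count table totals 9754102, which is 3.167 times the 3080106 host reads of the matched entry, against about 1 time in the other 3, so its 48.42 may belong to another library and the interval does not cover this.

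For YuA early library 3, the test with thinned controls and that of libraries 1 and 2 were written before their results were seen, and the strand test after. The library followed the authors' antisense means (0.846) more closely than their sense means (0.249), as would counts taken on the opposite strand. Too few counts alone did not account for this, because controls thinned to its coding count of 135893 kept a sense correlation of 0.896 to 0.911 in 20 draws. A host response remained open: over the 584 genes called early, libraries 1 and 2 moved by a median of 0.82 log2 units, 0.279 of the 2.93 of library 3, but these libraries entered the call, so this does not decide, and without library 3 only 23 genes were called. Counts were read as holding both strands from other libraries, a reading at odds with this library.

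For 14-1 the composition test was written before its result was seen and the length trend after. Most 14-1 libraries hold a higher coding share than the controls, so their rises could come from composition. Over 572 to 764 genes called without them, the early libraries 1 and 2, of lower share, moved by a median of 0.454 log2 units against 1.23 in the other 5. This was a share of 0.37 (0.288 to 0.456 over 6 pairs of held-out controls), which left composition open. The other 5 include early library 3, also from 3 min, with a coding share of 95.5%. The rest of them came from 6 or 12 min, when infection was further advanced. Early library 3 was not set apart in this test. With the coding share as a covariate, chosen after, the count fell from 837 to 143, and with only libraries under 60% share, also chosen after, to 162, so composition may account for much of it, although both settings remove part of the infection as well. A trend with length did not explain the count, which was 894 with the trend taken off and 837 before, without YuA early library 3.

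For nrdA, nrdB and thyA in the PEV2 late library the test was chosen after the result. Phages can carry genes of these kinds, and phage reads placed on the host gene would look like a rise. The host neighbour PA0343 of thyA was 3.7 log2 units above the highest control and PA1154, beside nrdB, 4.64, so reads are not limited to the genes themselves. For thyA this counted against misplaced phage reads, while for nrdA and nrdB the question stayed open, and antisense reads make up 83.6% of PA0343 and 73.8% of PA1154 in the authors' means. On the upstream side lgt, beside thyA, and PA1157, beside nrdA, did not rise. They held 75.8 and 117 CPM in that library, against 127 to 169 and 99.6 to 136 in the controls. Lipid A modification, also tested after its values were seen, differed between YuA and 14-1 (camera p = 6.7e-05 in limma with an estimated correlation of 0.424), but the fall in YuA alone produces this, and in 14-1 the tests disagreed. On balance the list was up there (fry adjusted p = 0.0201, with 10 of 12 values above 0), but whether it rose beyond other genes stayed open, with adjusted p = 0.547 with an estimated correlation.

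Splits of the libraries into groups at random were written before the results, except those of the core comparison and all without YuA early library 3, which were chosen after. They give the number with at least as many calls as the real grouping, itself included. In pooled comparisons this was 2 of 100 splits for LUZ19 (real 151, highest other 268), 5 of 100 for YuA (61, 577), 1 of 35 for PEV2 (23, 18) and 2 of 100 for 14-1 (275, 291). Without YuA early library 3 it was 2 of 100 splits (702, 1009), 1 of 100 (132, 5), 1 of 35 (53, 31) and 2 of 100 (837, 865). In single phases it was 1 of 35 splits for LUZ19 early (19, 3), LUZ19 late (145, 0), YuA early (584, 78), YuA late (40, 1) and 14-1 early (120, 2), and without that library 1 of 35 splits for LUZ19 early (184, 20), LUZ19 late (647, 8), YuA late (159, 5) and 14-1 early (683, 19).

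The core comparison had 4 of 100 splits (55, 1110), the test between 4 phages 1 of 100 splits (2593, 309; without YuA early library 3, 1 of 100 splits, 3175, 191) and the shared response 100 of 100 splits (0, 1; without that library 1 of 100 splits, 1, 0). Every split has at least 0 calls, so the shared response with all libraries could not be judged this way. Late against early had too few splits to judge: 10 of 10 splits for LUZ19 (0, 0; without that library 2 of 10 splits, 2, 9) and 10 of 10 splits for YuA (0, 55). The smallest possible share with 35 splits is 1 of 35. With all libraries, the splits with the most calls kept all 4 controls together for LUZ19, YuA and the core comparison. For 14-1 that split exchanged 1 control with 1 infected library. These splits still hold part of the contrast with the controls.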

How the results depend on the processing

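The limits of the data bear on every count. Phages differ in time as well as kind, controls came only from before infection, PEV2 had 1 library per phase, and whether libraries of a group are separate cultures is not stated. Most counts were higher when YuA early library 3 was left out of the edgeR fit. All libraries of a fit share the estimate of the spread, so this library also enters comparisons without YuA. Its median correlation with the controls was 0.354, against 0.85 to 0.976 in the other libraries. Without it LUZ19 went from 151 to 702 and 14-1 from 275 to 837. Counts and SE with all libraries thus depend on it, and how much of the change comes from the shared spread was not tested. Counts with all 29 libraries, edgeR and the settings fixed before the data were seen were 151 in LUZ19, 61 in YuA, 23 in PEV2, 275 in 14-1, 19 in LUZ19 early, 145 in LUZ19 late, 584 in YuA early, 0 in YuA middle, 40 in YuA late, 120 in 14-1 early, 190 in 14-1 middle, 306 in 14-1 late, 0 in LUZ19 late against early, 0 in YuA late against early, 151 in 14-1 late against early, 55 in the core comparison, 2593 in the test between 4 phages and 0 in the response shared by 4. A count is called moved when it changed by more than 1.5 times; counts not printed for a setting stayed within that range.

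Changes of the threshold and scaling moved these counts, all fixed before the data were seen. At an adjusted p under 0.01 they moved to 15 in LUZ19, 16 in YuA, 4 in PEV2, 54 in 14-1, 7 in LUZ19 early, 21 in LUZ19 late, 7 in YuA early, 0 in YuA late, 0 in 14-1 early, 59 in 14-1 middle, 77 in 14-1 late, 32 in 14-1 late against early, 1 in the core comparison and 1430 in the test between 4 phages (all lower; edgeR). A fold change of at least 1 log2 unit as well left 1228 in the test between 4 phages. With the total host count as the only scaling they moved to 239 in LUZ19, 9 in PEV2, 45 in LUZ19 early, 250 in LUZ19 late, 2047 in YuA early, 18 in YuA late, 830 in YuA late against early and 25 in the core comparison. Library sizes over all features moved only YuA middle, to 2. DESeq2 size factors within edgeR, no filter and the intersection of tests moved none.

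The DESeq2 test called more genes, and every count it moved was higher. It gave 467 in LUZ19, 342 in YuA, 43 in PEV2, 640 in 14-1, 85 in LUZ19 early, 322 in LUZ19 late, 1334 in YuA early, 22 in YuA middle, 106 in YuA late, 323 in 14-1 early, 480 in 14-1 middle, 562 in 14-1 late, 12 in LUZ19 late against early, 409 in YuA late against early, 373 in 14-1 late against early and 213 in the core comparison. The mean of the 3 phases in place of pooled libraries moved the counts to 338 in LUZ19, 97 in YuA, 7 in PEV2 and 495 in 14-1. A fit of only the samples of the 2 groups compared, which takes its spread from those alone, moved them to 1228 in LUZ19, 19 in YuA, 0 in PEV2, 770 in 14-1, 841 in LUZ19 early, 868 in LUZ19 late, 0 in YuA early, 15 in YuA middle, 244 in YuA late, 194 in 14-1 early, 1844 in 14-1 middle, 2050 in 14-1 late and 5 in 14-1 late against early.

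With a replicate block, fixed before the data were seen, which treats equal replicate numbers as paired, the counts moved to 52 in LUZ19, 20 in YuA, 0 in PEV2, 122 in 14-1, 0 in LUZ19 early, 65 in LUZ19 late, 4 in YuA early, 9 in YuA late, 0 in 14-1 early, 198 in 14-1 late, 82 in 14-1 late against early and 0 in the core comparison. The same replicate block with YuA early library 3 left out, chosen after seeing the data, moved them to 402 in LUZ19, 0 in PEV2, 622 in 14-1, 74 in LUZ19 early, 496 in LUZ19 late, 2 in YuA early, 121 in YuA late, 496 in 14-1 early, 711 in 14-1 middle, 759 in 14-1 late, 448 in 14-1 late against early and 0 in the core comparison. Evidence of pairing was mixed: 20 of 87 same-number pairs of libraries from different groups had a residual correlation over 0.1, with a median of 0.005 and a range from -0.549 to 0.439. No same-number pair of a control and a LUZ19 library was over 0.049, so controls and LUZ19 libraries share only a number. Pairing within the LUZ19 libraries still bears on their pooled comparison, which counted them as independent. Pairing of 14-1 middle with late libraries (0.382 for both pairs), which the rule could not take up, would bear on the pooled 14-1 comparison likewise. With the replicate block over all libraries 17 of 31 named LUZ19 calls were lost, and 0 with YuA early library 3 left out as well. Of 15 pairs of groups with 3 shared numbers, none had every library closest to its own number. For LUZ19 late against early, where the numbers were taken as pairs, a replicate block over those libraries alone, chosen after seeing the data, left 0 genes (edgeR; 326 had an unadjusted p under 0.05, and DESeq2 called 12 without the block), gave 8 without YuA early library 3 and added a camera call of type VI secretion HSI-I. With all 29 libraries it changed no other call. The main comparisons had no block.

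The remaining settings, and the core comparison itself, were chosen after seeing the data. Without the 3 libraries with the fewest coding counts the counts moved to 848 in LUZ19, 177 in YuA, 58 in PEV2, 971 in 14-1, 238 in LUZ19 early, 306 in LUZ19 late, 18 in YuA early, 2 in YuA middle, 165 in YuA late, 757 in 14-1 early, 877 in 14-1 middle, 949 in 14-1 late, 665 in 14-1 late against early and 1 in the response shared by 4. With the coding share of each library as a covariate and YuA early library 3 left out they moved to 893 in LUZ19, 268 in YuA, 92 in PEV2, 143 in 14-1, 248 in LUZ19 early, 1036 in LUZ19 late, 70 in YuA early, 53 in YuA middle, 240 in YuA late, 670 in 14-1 early, 3 in LUZ19 late against early, 690 in 14-1 late against early and 167 in the core comparison. Only libraries with a coding share under 60%, again without that library, gave 1206 in LUZ19, 337 in YuA, 0 in PEV2, 162 in 14-1, 230 in LUZ19 early, 231 in LUZ19 late, 0 in YuA early, 5 in YuA middle and 224 in the core comparison. With each library's trend with coding length taken off, without that library, they moved to 732 in LUZ19, 164 in YuA, 47 in PEV2, 894 in 14-1, 195 in LUZ19 early, 615 in LUZ19 late, 17 in YuA early, 17 in YuA middle, 172 in YuA late, 706 in 14-1 early, 746 in 14-1 middle, 772 in 14-1 late, 10 in LUZ19 late against early and 446 in 14-1 late against early.

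Leaving out each of the 29 libraries in turn gave these lowest and highest counts, with the number of omissions that moved the count. For pooled phages: LUZ19, 15 without control 1 to 702 without YuA early 3 (13 moved); YuA, 13 without control 2 to 132 without YuA early 3 (5 moved); PEV2, 0 without PEV2 late 2 to 59 without PEV2 middle 2 (8 moved); 14-1, 70 without control 2 to 837 without YuA early 3 (11 moved). For single phases the ranges were LUZ19 early, 1 without control 1 to 184 without YuA early 3 (11 moved), LUZ19 late, 31 without LUZ19 late 2 to 647 without YuA early 3 (6 moved), YuA early, 23 without YuA early 3 to 1333 without YuA early 1 (7 moved), YuA middle, 0 to 16 without YuA early 3 (13 moved), YuA late, 1 without YuA late 3 to 159 without YuA early 3 (14 moved), 14-1 early, 0 without control 1 to 683 without YuA early 3 (17 moved), 14-1 middle, 3 without 14-1 middle 2 to 827 without YuA early 3 (8 moved), 14-1 late, 22 without 14-1 late 1 to 891 without YuA early 3 (7 moved). Elsewhere they were LUZ19 late against early, 0 to 5 without LUZ19 late 1 (4 moved), YuA late against early, 0 to 479 without YuA early 2 (2 moved), 14-1 late against early, 8 without 14-1 late 1 to 603 without YuA early 3 (4 moved), the core comparison, 1 without control 2 to 84 without PEV2 middle 2 (5 moved), the response shared by 4, 0 to 1 without YuA early 3 (1 moved), the test between 4 phages, 2193 without 14-1 early 3 to 3175 without YuA early 3 (0 moved).

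Over the 7 comparisons and 32 lists, camera with its preset correlation called 85 of 224 list tests. With an estimated correlation this moved to 1 and with fry to 31, and without YuA early library 3 camera called 89. Among values of named genes, settings fixed before the data were seen left 988 the same, 154 weaker and 11 stronger, leaving out 1 library 3672, 584 and 7, and those added later 609, 81 and 21. A total of 2 values were reversed, both for dnaK in 14-1 and neither called: -0.56 with the coding share as a covariate and -0.46 in only the libraries with a coding share under 60%.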

Other observations

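A group of genes outside the fixed lists, chosen after their values were seen, rose in PEV2 infection. They lie side by side, and pncB1 and nadE belong to the salvage of NAD, the cofactor of redox metabolism, from nicotinate. The nicotinate phosphoribosyltransferase gene pncB1 rose by 3.92 ± 0.73 on the log2 scale (3 against 4 libraries, edgeR adjusted p = 0.00934), its neighbour PA4918 by 3.64 ± 0.75 (adjusted p = 0.021), the NAD synthetase gene nadE by 3.44 ± 0.80 (adjusted p = 0.0446) and PA4921, annotated as a cholinesterase gene, by 2.53 ± 0.60 (adjusted p = 0.0446), while PA4917 stood at 2.77 (adjusted p = 0.282). The run extends to PA4916, at 3.51 ± 0.75 (adjusted p = 0.0251), and PA4915, a probable chemotaxis transducer gene, at 2.24 ± 0.53 (adjusted p = 0.0446). None of these was called in LUZ19, YuA or 14-1, but some libraries there were above the controls: PA4917 held 365 to 756 CPM in 4 YuA libraries against 64.3 to 88.4 in the controls, and nadE 299 to 394 and pncB1 211 to 320 in the middle and late 14-1 libraries. The run is therefore not shown to be particular to PEV2. The rise lies in the late library, with 4780 CPM for pncB1 and 4290 for nadE against 105 to 122 and 108 to 160 in the controls.

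A hypothesis is that late PEV2 infection drains NAD. Against a response limited to NAD genes, the neighbours PA4915 and PA4921 rose as well. The late library also holds the rise of nrdA, nrdB and thyA, for which the downstream neighbours PA0343 and PA1154 lay 3.7 and 4.64 log2 units above the highest control. The upstream neighbours did not rise there. In that library lgt, beside thyA, held 75.8 CPM (127 to 169 in the controls) and PA1157, beside nrdA, 117 (99.6 to 136). A local spread of transcription, seen at those genes only downstream, could be an alternative. Measuring NAD and its precursors over a PEV2 infection with time-matched uninfected cultures, with 3 or more late libraries mapped to host and phage together, would separate the 2 accounts.

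In YuA 9 of 12 lipid A modification genes fell, with a median of -1.40 log2 units over the 12. The arn genes answer to magnesium and to cationic peptides through regulators that include phoP, which fell by 1.53 ± 0.35 in YuA. In LUZ19, however, phoP fell by 1.72 ± 0.36 while arnB (-0.54 ± 0.26) and arnE (-0.37 ± 0.38) were not called. Smaller falls of the arn genes there could have been missed, so this leaves open whether lower phoP is the only cause. A hypothesis is that YuA changes another input to the arn genes. Counts of arnB in cells with and without added magnesium, infected by YuA or LUZ19 beside mock-infected cells, would test it.

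In 14-1, 12 of 36 pyoverdine and pyochelin genes, all in the pyochelin cluster, rose and 7 of 20 O-antigen genes fell between early and late libraries. Both list calls were lost with an estimated correlation (adjusted p = 0.499 and adjusted p = 0.187). Their levels had moved by the middle libraries, with pchF at 765 and 696 CPM there and 767 and 730 late, and wzy at 78.3 and 83.8. The early libraries lay on the other side of the controls for pchF (46.5 to 139 against 250 to 336) and partly for wzy (415 to 1090 against 265 to 453). Both changes could follow the age of the culture, since no uninfected library at 12 min was analysed here, and the early library 1 differed from the rest, as its arnA level of 135 shows beside 269 to 374. Uninfected cultures sampled at 3, 6 and 12 min would show whether the change needs the phage.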
